A study of Mus musculus with 12 samples.

How the data were processed

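The series holds 12 strand-specific, poly(A)-selected RNA-seq libraries of mouse hippocampus, 3 each from mice given vehicle, an siRNA against GSK3β, L803mts or ketamine. Group and replicate number were taken from the library titles. The authors deposited 3 tables, each comparing 1 treatment with the same 3 control libraries. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks and Cuffdiff were used; the versions of the latter were not given in the sources used here. The notes list the builds GRCh37 and NCBIM37 without saying what each was used for. The largest chromosome 7 coordinate of the tables, 152125580, lies beyond the last GRCm38 gene end on that chromosome, 145324059, so coordinates are given on the mouse build NCBIM37. No annotation of that build was used here, and exons or untranslated regions are not assigned. GRCm38 annotation served for this check of the build and, by gene name, for GC content and transcript length.

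The deposited tables give, per the file headers, an FPKM value for each library and group, a log2 fold change, a p-value and an FDR for each locus. FPKM values are fragment counts scaled to transcript length and library size, normalised by the authors within each table. Locus identifiers and limits differ between tables, so tests were made only within a table and genes were joined by name. The deposited log2 fold change equals the log2 ratio of the library means within 0.001 at all but 4, 3 and 3 loci of the siGSK3b, L803mts and ketamine tables. The authors' p-value has a floor of 5e-05, so the smallest FDR (q-value) is 0.0126, 0.0119 and 0.0157. The deposited FDR follows Benjamini-Hochberg adjustment over the loci with a p-value below 1, here called tested. At 10.2%, 9.28% and 9.48% of the loci the deposited group value differed by over 1% from the mean of its 3 libraries, and group values were not used. A spreadsheet had turned 21 gene names per table into dates, and these were not matched to lists.

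Depth cannot be recovered from FPKM. Only 32, 17 and 21 low loci were usable in a search for steps of single reads, and no interval or detection floor is given. A locus listed at 0 is reported as such. In the L803mts and ketamine tables a single very short locus took 43.2% to 86.6% of the FPKM sum of a library, while the median FPKM differed little between libraries.

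The main result is the authors' own test, with loci at an FDR of at most 0.05 taken as called. The design fixed before the data were examined foresaw limma beside it if the tables held values per library, which they did. Limma 3.58.1 (R 4.3.3) with an intensity trend was fitted to log2(FPKM + 1) of the 6 libraries of a table, over the tested loci without a further filter, and p-values were adjusted by Benjamini-Hochberg. A fold change on that scale understates the change of low loci. With 3 against 3 libraries the smallest exact permutation p is 0.1, so no permutation test of single genes was made. On simulated tables limma recovered 76%, 86% and 78% of loci changed 2-fold and 100% of those changed 4-fold in the siGSK3b, L803mts and ketamine settings, with 14, 20 and 15 false calls. These tables had independent normal noise at each locus, and changes were set on log2(FPKM + 1) at loci with a mean of at least 1 FPKM. They held no single outlying library and no spread shared between genes, so these shares do not give limma's power on the real tables.

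Before the data were examined, 32 gene lists were fixed, covering pathways and cell types of the hippocampus and of neighbouring tissue. The list of mitochondrially encoded genes had no measured member. Each list was tested for enrichment of called loci with a two-sided Fisher's exact test against the other named loci tested in the table, adjusted over 93 tests. Calls were also readjusted over the list alone, each list's median fold change was ranked among 10000 random lists of the same size and similar expression, and limma's fry tested the lists with libraries as replicates. Fry was added after the data were seen. Members of a list vary together within a library, which Fisher's exact test ignores.

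The genes named in the text follow a rule fixed in advance. It takes Gsk3b, Gsk3a and Igf2; the 8 called genes with the largest fold change in each direction at a mean of at least 1 FPKM in the higher group and above 0 in both; up to 4 called members of each list with 2 or more calls; 2 members of highest control level of lists without a call; genes called in all 3 comparisons; and genes called in opposite directions. Other genes are marked as singled out after their values were seen. Names without an official symbol were passed over.

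For shared controls, unchanged groups were simulated 200 times. The design meant to take standard errors from the deposited p-values, and the spread between libraries was used instead because the tables hold it. The overlap of independent lists was computed per direction from the calls among genes tested in both tables. Alternatives were an FDR of at most 0.01 or 0.1, a minimum absolute log2 fold change of 0.5, a minimum mean of 1 FPKM, the log2(FPKM + 1) scale, median-centred values, genes on a single locus, control values within 10% between tables, the replicate number as a block, and leaving out each library. For the authors' calls a left-out library was judged by whether the log2 fold change of the library means kept at least 0.5 of its size. A pseudocount of 0.1, calls with libraries that do not overlap, and fry were added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.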

Results

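RNA-seq libraries were prepared from poly(A)-selected RNA of the hippocampus of C57BL/6 mice, with 3 libraries in each of 4 groups. Control mice received vehicle intranasally at 5 µL per nostril every other day for 3 days. On the same schedule a group labelled siGSK3b received 10 µg of an siRNA against GSK3β, and another received 60 µg of L803mts, an inhibitor of GSK3. GSK3β is a serine/threonine kinase that marks β-catenin for degradation. Ketamine, an antagonist of NMDA-type glutamate receptors, was given intraperitoneally at 10 mg/kg and RNA was taken at 24 h. The labels list a single control group, so ketamine was compared with intranasal vehicle, and route and drug were not separated. The 3 tables gave FPKM values for 16687 loci (siGSK3b against control), 17394 loci (L803mts) and 17864 loci (ketamine). The median FPKM per library lay between 8.66 and 10.2, and the read depth is unknown because FPKM keeps no counts. The labels do not say that the libraries came from separate mice, so the tests below measure the spread between libraries, whether biological or technical. Means are given ± SD over 3 libraries per group, and each table was normalised separately and drew its own locus limits, so levels are compared only within a table.

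The targeted gene, Gsk3b (chromosome 16, 38243242 to 38247469, build NCBIM37), was not lower in the libraries labelled siGSK3b. Its FPKM was 18.4, 19.3 and 18.9 in these libraries and 18.0, 17.3 and 17.8 in the control libraries of the same table. The difference on the log2(FPKM + 1) scale was 0.09 with a standard error of 0.09 (limma, adjusted p = 0.938, higher in 3 of 3 libraries). The level of this locus goes against the label at the mRNA level. Which part of the Gsk3b transcript the locus covers was not assigned, and other parts are not judged. Directions below refer to the libraries labelled siGSK3b. The position of the siRNA target was not given in the sources used here. In the L803mts table Gsk3b was at 17.3, 18.2 and 22.2 FPKM with the inhibitor and at 18.1, 17.5 and 18.1 in control. In the ketamine table it was at 16.5, 18.4 and 18.0 FPKM with ketamine and at 18.6, 17.5 and 18.2 in control. Gsk3a, the paralog, was at 18.4 ± 2.31 in control and 19.8 ± 1.84 with L803mts, and at 18.4 ± 2.17 in control and 17.5 ± 0.758 with ketamine. In the siGSK3b table its locus was joined with Erf, and the joint value was 30.5 ± 2.90 in control and 28.4 ± 4.61 in the libraries labelled siGSK3b. No member of the fixed list of WNT and β-catenin pathway genes passed the authors' Cuffdiff test, among 21, 26 and 23 measured in the siGSK3b, L803mts and ketamine tables. At an unadjusted p under 0.05 the same test had 1 member higher with siGSK3b, 1 higher with L803mts and 2 lower with ketamine, and limma had 1 lower, 3 higher and 2 lower. Fzd4, a WNT receptor gene outside that list and singled out after its values were seen, did pass, at 4.31 ± 0.740 FPKM against 2.41 ± 0.974 with siGSK3b and 4.10 ± 0.408 against 2.44 ± 0.977 with L803mts. In the authors' deposited tables its log2 fold changes were 0.84 and 0.75, and without control replicate 1, the highest control library, they were 1.22 and 1.13. Ctnnb1, which encodes β-catenin, was at 102 ± 8.68 FPKM in control and 93.5 ± 6.39 in the libraries labelled siGSK3b, at 148 ± 16.4 and 141 ± 11.9 in the L803mts table, and at 87.8 ± 7.24 and 73.2 ± 3.79 in the ketamine table. Its locus in the L803mts table (chromosome 9, 120861995 to 120872144) does not overlap those of the siGSK3b (120838860 to 120860920) and ketamine (120838124 to 120860920) tables.

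**Figure D1:**
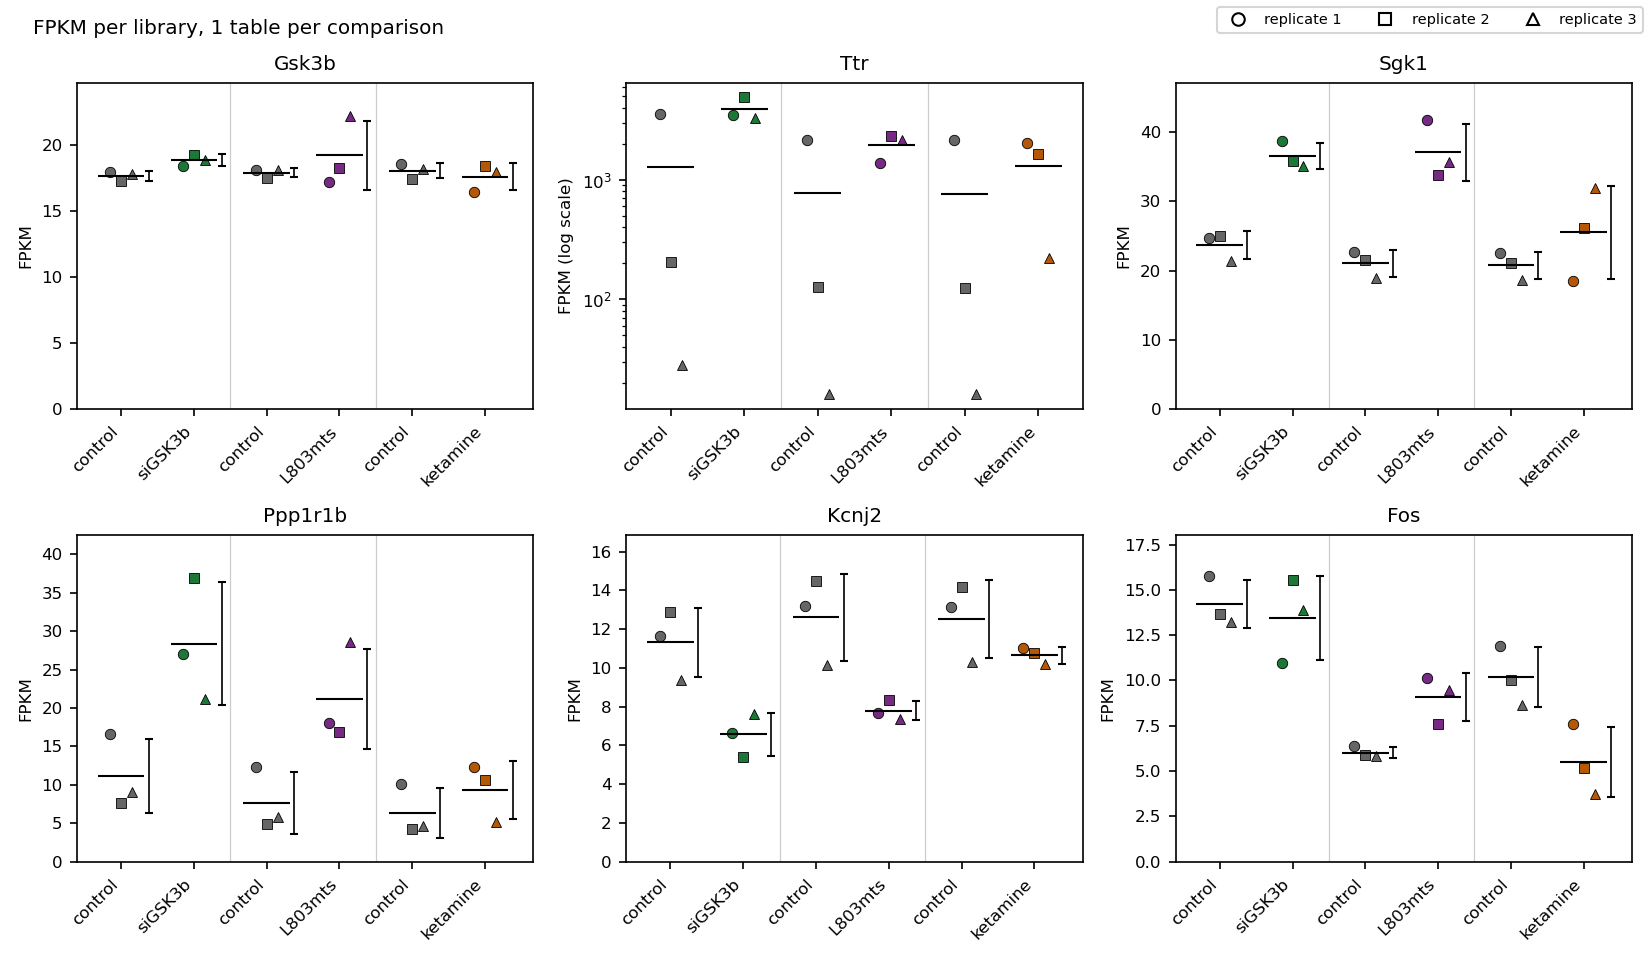
FPKM of 6 genes (y axis, logarithmic for Ttr) in each library, by group (x axis), with the table of each comparison set apart by a vertical line; symbols are libraries, horizontal bars group means, and error bars the SD over 3 libraries (not drawn for Ttr). Gsk3b stood between 16.5 and 22.2 in every library shown, Ttr differed between control libraries from 28.0 to 3579 in the siGSK3b table, and Sgk1 was above every control library with siGSK3b and L803mts.

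The siGSK3b comparison asks which transcripts differed after the siRNA was given. Choroid plexus genes, expressed by the ventricular epithelium that makes cerebrospinal fluid, had higher means in the libraries labelled siGSK3b, but control replicate 1 was as high and the list did not pass with libraries as replicates (limma's fry, adjusted p = 0.481). Of 21 measured members of this list 15 rose and 0 fell, and 19 rose adjusted over the list alone. Ttr (chromosome 18, 20799457 to 20832846), which encodes the thyroid hormone carrier transthyretin, had a mean of 3890.3 ± 876 FPKM against 1270.1 ± 2001 in control. Lbp was at 17.8 ± 13.1 against 3.77 ± 5.11, Tmem72 at 13.4 ± 3.28 against 4.14 ± 6.30, and F5, the gene of coagulation factor V, at 19.96 ± 7.42 against 6.54 ± 10.0. In the authors' deposited table their log2 fold changes were 1.61 (Ttr), 2.24 (Lbp), 1.69 (Tmem72) and 1.61 (F5), each with an FDR of 0.0126. The control libraries were far apart. The mean log2(FPKM + 1) over the list was 4.63, 2.17 and 1.55 in control replicates 1, 2 and 3, and 4.39, 4.90 and 4.44 in the libraries labelled siGSK3b. The median log2 ratio of the treated mean to control replicate 1 was −0.03, against 2.25 and 2.82 for control replicates 2 and 3. Without control replicate 1 the log2 fold changes of Ttr, Lbp, Tmem72 and F5 were 5.07, 4.43, 4.71 and 4.75. Without control replicate 3 those of Ttr, Tmem72 and F5 were 1.04, 1.12 and 1.06, and without siGSK3b replicate 2 that of Lbp was 1.45.

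Outside the choroid plexus list, Sgk1 (chromosome 10, 21602096 to 21719598), a kinase induced by glucocorticoids, rose from 23.7 ± 2.04 to 36.5 ± 1.91 FPKM. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, rose from 11.1 ± 4.80 to 28.4 ± 7.98. As for the choroid plexus genes, control replicate 1 was the highest control library for Ppp1r1b, with 16.6, 7.66 and 9.10 FPKM in control replicates 1, 2 and 3. Kcnj2 (chromosome 11, 110927525 to 110938351), an inwardly rectifying potassium channel gene, fell from 11.3 ± 1.78 to 6.57 ± 1.11. Mobp, a myelin protein gene, fell from 78.2 ± 3.97 to 58.4 ± 0.915. For these 4 genes every library labelled siGSK3b lay on the same side of every control library. In the authors' deposited table their log2 fold changes were 0.63, 1.35, −0.79 and −0.42, with an FDR of 0.0126 for all but Mobp (0.0224). Sgk1, Kcnj2 and Mobp were singled out after their values were seen. Of 14 neocortical neuron markers Tshz2 and Mef2c fell, from 4.46 ± 1.34 to 2.78 ± 0.366 and from 54.9 ± 7.63 to 38.7 ± 2.48. The log2 fold change of Tshz2 was −0.68 in the authors' deposited table and −0.45 without control replicate 2. Of 13 genes of IGF and insulin signalling Igf2 and Igfbp2 rose. Igf2 (chromosome 7, 149836673 to 149838273), which encodes insulin-like growth factor 2 and is also a marker of meninges and choroid plexus, was at 12.1 ± 5.80 against 7.56 ± 4.38, and Igfbp2 at 55.6 ± 15.7 against 30.3 ± 22.4. The authors' deposited table gave Igf2 a log2 fold change of 0.68, which was 0.22 without siGSK3b replicate 2 and 1.26 without control replicate 1, and Igfbp2 0.87, which was 1.68 without control replicate 1. Of 47 ribosomal protein genes Rplp1 and Rplp2 fell, with log2 fold changes of −1.30 and −0.90 in the authors' deposited table and of −0.32 and −0.38 without control replicate 2. Of the 47 genes 32 were below control and 6 fell adjusted over the list alone, with a list mean in log2(FPKM + 1) of 4.81, 4.81 and 4.74 against 4.79, 5.02 and 4.99 in control (limma's fry, adjusted p = 0.481).

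Several of the largest fold changes came from a single library. Rnf182, a ubiquitin ligase gene, was at 99.8 FPKM in siGSK3b replicate 1 and at 5.09 and 5.48 in the other libraries of that group, against 4.03 ± 0.683 in control. The joint locus of Dgkq and Slc26a1 was at 287 FPKM in siGSK3b replicate 3 and Kif24, a kinesin gene, at 21.3, against control means of 13.3 ± 0.791 and 1.31 ± 0.854. Without these libraries the log2 fold changes were 0.39, 0.27 and 0.19. Kcnj3, a G protein-gated potassium channel gene, was at 507, 42.0 and 235 FPKM against 42.3 ± 3.03 in control, and Immp2l at 14.4 ± 8.37 against 3.71 ± 1.09. The log2 fold change of Kcnj3 was 2.63 in the authors' deposited table and 1.71 without siGSK3b replicate 1. Sult1c2, a sulfotransferase gene, and the joint locus of Apbb2 and Rbm47 had log2 fold changes of 1.95 and 1.71 in the authors' deposited table and of 4.81 and 4.56 without control replicate 1. On the lower side Adamts20, a metalloprotease gene, was at 46.9 FPKM in control replicate 2 and at 0.818 and 1.97 in the other control libraries, against 1.00 ± 0.249. Its log2 fold change of −4.04 in the authors' deposited table was −0.47 without that library. The changes of Vps37d, Hist1h4d, Ndufa12 and Atp6v0c, the latter a subunit gene of the vacuolar proton pump, were −2.51, −1.97, −1.78 and −2.02 in the authors' deposited table and −0.72, −0.16, −0.90 and −1.05 without control replicate 2. Lrp3 fell from 5.53 ± 2.09 to 2.01 ± 0.980 and Gcnt4 from 3.79 ± 1.99 to 1.31 ± 0.405. Tnrc6a, a gene of microRNA-guided silencing, was at 55.0, 62.6 and 332 FPKM against 56.7, 757 and 897 in control, with a log2 fold change of −3.28 without siGSK3b replicate 3.

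In all, 83 of 16351 tested loci had an FDR of at most 0.05 in the authors' deposited table, 46 higher and 37 lower in the libraries labelled siGSK3b. The 2 groups' libraries did not overlap at 32 of these loci, or 38.6% against 10.6% of all tested loci and 10% by chance. The calls were picked for a group difference in these same libraries, which by itself raises this share, so it is no separate support. Fisher's exact test across genes gave an adjusted p of 3.2e-28 for choroid plexus, 0.0257 for IGF and insulin signalling and 0.0269 for neocortical markers. It gave 0.0567 for the meningeal list (2 of 25 called) and 0.176 for ribosomal proteins. Igf2 and Igfbp2 are on both the IGF and the meningeal list and were the 2 calls of each, so these are not separate results. Fisher's test counts genes and not libraries. With libraries as replicates, limma's fry found no list moved in 1 direction (adjusted p = 0.481 for choroid plexus, 0.491 for IGF and insulin signalling and 0.481 for neocortical markers). On log2(FPKM + 1) limma called 1 locus at an adjusted p of at most 0.05 and 953 loci at an unadjusted p under 0.05. Without control replicate 1 limma called 36 loci, of which 33 were higher.

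**Figure D2:**
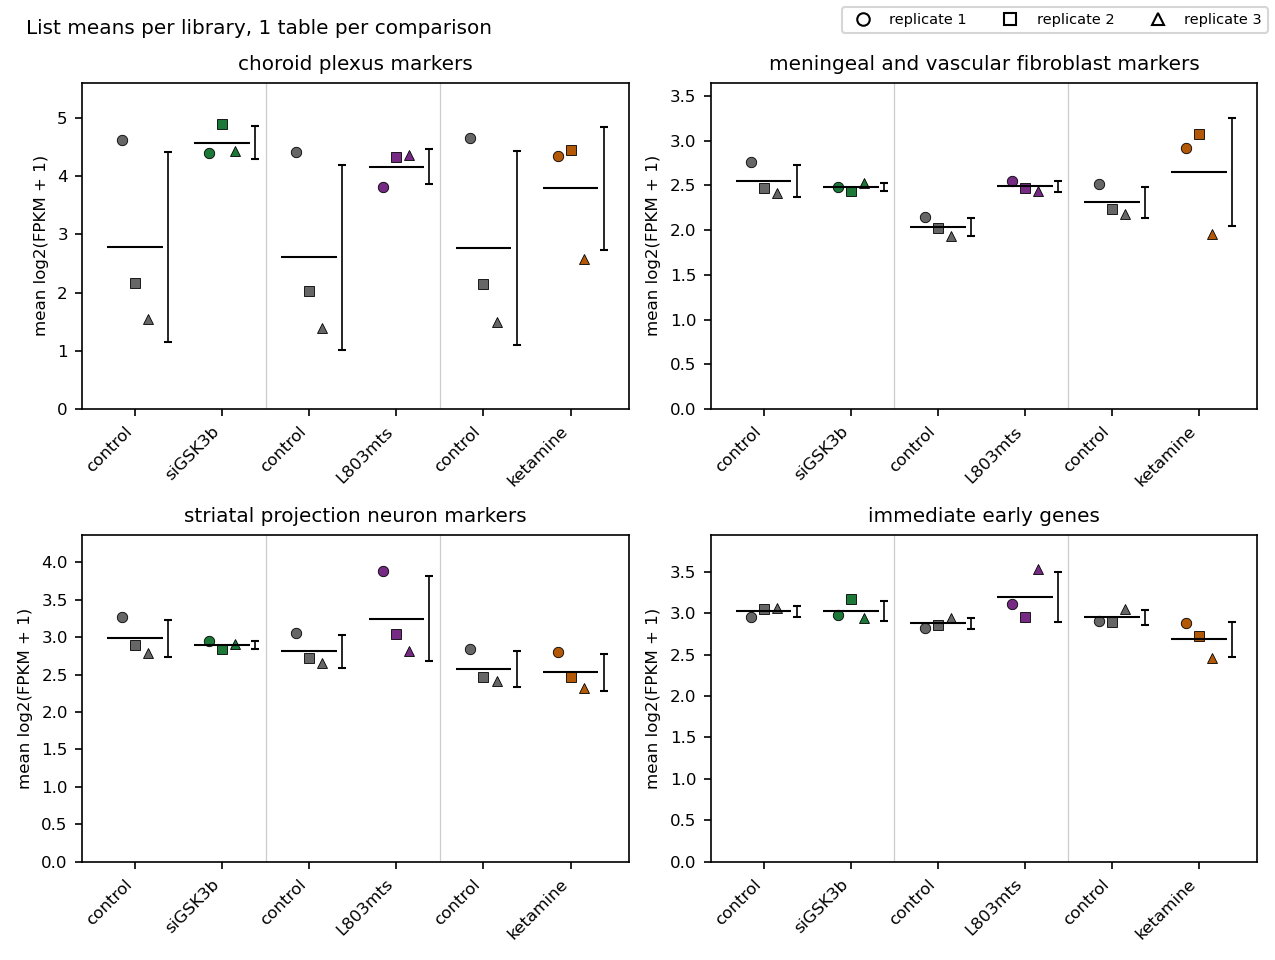
Mean log2(FPKM + 1) over the measured members of 4 gene lists (y axis) in each library, by group (x axis), with the table of each comparison set apart by a vertical line; symbols are libraries, horizontal bars group means, and error bars the SD over 3 libraries. Choroid plexus means in control ran from 1.55 to 4.63 in the siGSK3b table, meningeal means with L803mts (2.44 to 2.55) lay above those of control (1.94 to 2.14), and immediate early gene means with ketamine (2.46 to 2.88) lay below those of control (2.89 to 3.06).

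The L803mts comparison asks which transcripts differed after the inhibitor. Markers of meninges and vascular fibroblasts had higher means with L803mts for 26 of 28 measured members, though the list did not pass for a shift in 1 direction (limma's fry, adjusted p = 0.202, and 0.0104 for change in either direction). Of the 28 members 4 rose and 0 fell, also adjusted over the list alone. Aebp1 (chromosome 11, 5764179 to 5767686), a matrix-binding protein gene, rose from 2.36 ± 0.178 to 7.11 ± 1.52 FPKM, and Fmod, which encodes the collagen-binding proteoglycan fibromodulin, from 1.41 ± 0.422 to 3.81 ± 0.376. Igf2 rose from 2.04 ± 1.20 to 4.77 ± 2.05 and Igfbp2 from 15.4 ± 10.9 to 29.9 ± 4.91. The Igf2 locus also had an antisense entry, at 5.90 ± 3.997 in control and 13.7 ± 4.69 with L803mts. In the authors' deposited table the log2 fold changes were 1.59 (Aebp1), 1.44 (Fmod), 1.22 (Igf2) and 0.96 (Igfbp2), with FDRs of 0.0119, 0.0119, 0.0199 and 0.0119. Without control replicate 1 those of Igfbp2 and of the antisense entry of Igf2 were 1.71 and 1.93. The list mean in log2(FPKM + 1) was 2.55, 2.48 and 2.44 with L803mts and 2.14, 2.03 and 1.94 in control. Plxdc1 (chromosome 11, 97785213 to 97817881), a gene of tumour endothelium, rose from 1.60 ± 0.389 to 5.38 ± 0.250, and Flt1, a VEGF receptor gene singled out after its values were seen, from 3.32 ± 0.246 to 5.43 ± 1.503. The log2 fold change of Flt1 was 0.71 in the authors' deposited table and 0.47 without L803mts replicate 3.

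Choroid plexus genes also had higher means with L803mts, but the list mean of control replicate 1 was higher than that of each L803mts library. The list did not pass with libraries as replicates (limma's fry, adjusted p = 0.491). Of 22 measured members 12 rose and 0 fell, and 18 rose adjusted over the list alone. Ttr was at 1949 ± 502 FPKM against 768 ± 1208, with 2162, 126 and 16.2 in the control libraries and 1376, 2308 and 2164 in the L803mts libraries. Tmem72 was at 14.4 ± 3.50 against 5.03 ± 7.64, Col8a1, a collagen gene, at 6.70 ± 1.85 against 2.84 ± 4.07, and F5 at 16.9 ± 5.37 against 7.22 ± 11.2. The list mean in log2(FPKM + 1) was 4.41, 2.03 and 1.39 in control replicates 1, 2 and 3 and 3.81, 4.33 and 4.36 with L803mts. The median log2 ratio of the treated mean was −0.27 over control replicate 1 and 2.08 and 2.60 over control replicates 2 and 3. The log2 fold changes of Ttr, Tmem72, Col8a1 and F5 were 1.34, 1.52, 1.24 and 1.23 in the authors' deposited table and 4.77, 4.53, 3.75 and 4.55 without control replicate 1. Without control replicate 3 they were 0.77, 0.95, 0.76 and 0.69.

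Some immediate early and synaptic genes rose with L803mts, though neither list passed fry. Of 19 immediate early genes Egr1, Nr4a1 and Arc rose and 0 fell, and 9 rose adjusted over the list alone. Egr1 (chromosome 18, 35021079 to 35023146), a zinc-finger transcription factor gene, was at 10.9 ± 8.05 FPKM against 3.48 ± 0.494, Nr4a1, an orphan nuclear receptor gene, at 4.40 ± 2.38 against 2.28 ± 0.569, and Arc, which acts in AMPA receptor endocytosis, at 29.5 ± 7.41 against 18.1 ± 4.20. Of 30 genes of synaptic vesicles and scaffolds 5 rose, and 11 rose adjusted over the list alone, among them Syp (synaptophysin), from 284 ± 26.6 to 428 ± 109, Syn1 (synapsin), from 9.72 ± 0.961 to 16.8 ± 10.6, Shank3, from 12.3 ± 5.38 to 22.1 ± 13.4, and Vamp2, from 44.0 ± 8.72 to 63.7 ± 21.4. L803mts replicate 3 held the highest value of each of these 7 genes. Without it the log2 fold changes of Egr1, Nr4a1, Arc, Syp, Syn1, Shank3 and Vamp2 were 0.87, 0.45, 0.48, 0.37, 0.14, 0.23 and 0.22, against 1.65, 0.95, 0.70, 0.59, 0.79, 0.85 and 0.53 in the authors' deposited table. The median log2(FPKM + 1) fold change was 0.29 over the immediate early list and 0.14 over the synaptic list, and 0.11 and 0.02 without that library. The synaptic median was also 0.02 without control replicate 1, and it was 0.32 without control replicate 3. Outside these lists Vgf, a neuropeptide precursor gene, rose from 9.55 ± 3.30 to 18.7 ± 5.11, and Slc32a1, the vesicular GABA transporter gene, from 1.55 ± 0.310 to 4.54 ± 2.0. Of 11 striatal neuron markers 3 rose, among them Ppp1r1b and Penk, and 5 rose adjusted over the list alone. L803mts replicate 1 stood out: the list mean in log2(FPKM + 1) was 3.89, 3.04 and 2.82 with L803mts and 3.06, 2.72 and 2.65 in control, and the list median of 0.57 was 0.06 without that library. Ppp1r1b was at 21.2 ± 6.49 against 7.66 ± 4.07. Unlike the list mean it was highest in L803mts replicate 3, with 18.1, 16.8 and 28.7 FPKM in replicates 1, 2 and 3. Control replicates 1, 2 and 3 were at 12.3, 4.86 and 5.77. Penk, the proenkephalin gene, was at 39.3 FPKM in L803mts replicate 1, and its log2 fold change was 0.89 in the authors' deposited table and 0.27 without that library. The same library was highest over the markers of thalamus and habenula, of which 12 of 16 were above control and 1, Zic1, rose (limma's fry, adjusted p = 0.481). The list mean was 3.43, 3.08 and 3.14 with L803mts and 3.02, 3.01 and 2.88 in control, and the list median of 0.24 was 0.06 without L803mts replicate 1. Sgk1 rose from 21.0 ± 1.98 to 37.1 ± 4.11 and Ddit4, an mTOR inhibitor gene induced by stress, from 4.47 ± 0.535 to 9.60 ± 2.74, both singled out after their values were seen.

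Of the genes that fell, Kcnj2 went from 12.6 ± 2.24 to 7.80 ± 0.501 FPKM, Cnksr2, a synaptic scaffold gene, from 7.66 ± 0.788 to 3.82 ± 0.691, and Slitrk5 from 22.7 ± 12.1 to 14.4 ± 1.41. The log2 fold change of Slitrk5 was −0.66 in the authors' deposited table and −0.13 without control replicate 2. Rplp1 was at 94.0 FPKM in control replicate 2 and at 17.8 and 30.2 in the other control libraries, and its log2 fold change was −0.02 without that library. Of 47 ribosomal protein genes 40 were below control and Rplp1 alone fell, with a list mean in log2(FPKM + 1) of 4.83, 4.64 and 4.63 with L803mts and 4.72, 4.92 and 4.87 in control (limma's fry, adjusted p = 0.481). The log2 fold changes of Adamts20 and Hist1h4d were −4.26 and −1.52 in the authors' deposited table and −1.24 and 0.28 without it, and that of Ttf2 was −1.56 without control replicate 3, against −2.82. On the higher side Nudt13 was at 116 FPKM in L803mts replicate 2, and its log2 fold change of 2.79 in the authors' deposited table turned to −0.28 without that library. Ttyh3 was at 3.67 ± 3.23 FPKM against 0.766 ± 0.302, Fancg, a DNA repair gene, at 8.76 ± 6.30 against 1.97 ± 0.531, and Paqr5 at 1.60 ± 0.276 against 0.529 ± 0.275. The log2 fold change of Ttyh3 was 2.26 in the authors' deposited table and 1.25 without L803mts replicate 3. H2-Ab1, an MHC class II gene singled out after its values were seen, was listed at 0 in the 3 control libraries and at 1.13, 0.948 and 0.328 FPKM with L803mts.

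In all, 111 of 17074 tested loci had an FDR of at most 0.05 in the authors' deposited table, 98 higher and 13 lower with L803mts. Libraries did not overlap at 47 of these loci, or 42.3% against 12.5% of all tested loci and 10% by chance. Picking calls on the same libraries by itself raises this share. Fisher's exact test across genes gave adjusted p-values of 7.1e-19 (choroid plexus), 9.7e-05 (synaptic), 0.00134 (meningeal), 0.00134 (striatal), 0.00536 (immediate early) and 0.0342 (IGF and insulin signalling), and 0.0501 for neuropeptides and neurotrophins. Igf2 and Igfbp2 were both calls of the IGF list and 2 of the 4 meningeal calls, so these 2 lists are not separate results. With libraries as replicates, limma's fry gave the meningeal list an adjusted p of 0.0104 for change in either direction and 0.202 for a shift in 1 direction. For a shift in 1 direction fry gave adjusted p-values of 0.491 (choroid plexus), 0.717 (synaptic), 0.596 (striatal), 0.481 (immediate early) and 0.419 (IGF and insulin signalling), so none of these lists passed with libraries as replicates, nor did any for change in either direction. Of 19 immediate early genes limma had 5 higher at an unadjusted p under 0.05. Over all loci limma called 0 at an adjusted p of at most 0.05 and 1055 at an unadjusted p under 0.05, and without control replicate 1 it called 36, all higher. Without L803mts replicate 3, 82 of the 111 loci kept at least 0.5 of their log2 fold change.

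The ketamine comparison asks which transcripts differed 24 h after the drug. Some immediate early genes fell with ketamine, and 17 of 20 measured members lay below control, but the list did not pass with libraries as replicates (limma's fry, adjusted p = 0.481). Of these Npas4, Fos and Btg2 fell and 0 rose, and 6 fell adjusted over the list alone. Npas4 (chromosome 19, 4985019 to 4987887), an activity-dependent transcription factor gene, fell from 1.72 ± 0.806 to 0.650 ± 0.167 FPKM, Fos (chromosome 12, 86817386 to 86818258) from 10.2 ± 1.64 to 5.51 ± 1.93, and Btg2 (chromosome 1, 135971588 to 135975694), an antiproliferative gene, from 9.36 ± 1.06 to 5.55 ± 0.873. Every ketamine library was below every control library for each of these 3 genes. In the authors' deposited table their log2 fold changes were −1.40, −0.89 and −0.76, each with an FDR of 0.0157. Arc, at 14.1 ± 3.58 in control and 9.75 ± 3.80 with ketamine, did not pass (FDR of 0.255 in the authors' deposited table).

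Some meningeal and choroid plexus genes rose with ketamine, through ketamine replicates 1 and 2. Of 24 meningeal markers Aldh1a2, a retinoic acid synthesis gene, and Ogn, the osteoglycin gene, rose, and 9 rose adjusted over the list alone. Aldh1a2 was at 11.9, 12.8 and 3.94 FPKM with ketamine against 5.06 ± 0.435, and Ogn at 20.8, 33.4 and 10.5 against 11.98 ± 2.84. Without ketamine replicate 2 the log2 fold change of Ogn was 0.39, against 0.85 in the authors' deposited table. Igf2 shared a locus with Th in the ketamine table, so no value of Igf2 alone is given. Of 22 choroid plexus genes Tmem72 and Kcne2, a potassium channel subunit gene, rose, and 9 rose adjusted over the list alone. Kcne2 was at 26.3, 23.5 and 2.67 FPKM with ketamine and at 28.5, 1.76 and 0.368 in control, so that its log2 fold change of 0.78 in the authors' deposited table was 4.04 without control replicate 1, 0.21 without control replicate 3 and 0.36 without ketamine replicate 1. That of Tmem72 was 0.89 in the authors' deposited table, 3.97 without control replicate 1, 0.31 without control replicate 3 and 0.30 without ketamine replicate 2. Lepr, the leptin receptor gene, was at 4.19, 5.25 and 0.633 FPKM against 1.47 ± 1.36, and its log2 fold change was 2.27 without control replicate 1 and 0.72 without ketamine replicate 2. The mean log2(FPKM + 1) over the choroid plexus list was 4.35, 4.46 and 2.57 with ketamine and 4.66, 2.15 and 1.503 in control.

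Other genes rose with ketamine. Gbp5, an interferon-induced GTPase gene, went from 1.20 ± 0.196 to 2.97 ± 1.55 FPKM (log2 fold change 0.79 without ketamine replicate 2), Slc22a27 and Slc22a29, organic anion transporter genes, from 7.52 ± 4.21 to 20.04 ± 2.13 and from 8.30 ± 3.49 to 20.9 ± 2.10, and an intronic locus of H60b from 2.54 ± 0.934 to 6.64 ± 0.985. These multigene families can share reads. Itih2 was at 72.7 FPKM and Trh, the thyrotropin-releasing hormone gene, at 5.58 in ketamine replicate 1, and their log2 fold changes of 3.06 and 2.86 in the authors' deposited table were 1.08 and 0.13 without that library. Rplp1 fell, from 17.6, 91.8 and 29.7 FPKM in control to 23.6, 21.4 and 24.7, and its log2 fold change was −0.02 without control replicate 2. Zfhx2 was at 39.4 FPKM in ketamine replicate 3, and its change of 1.54 in the authors' deposited table was 0.87 without that library. Among the loci that rose, 18 of 54 were protein-coding and 21 were pseudogenes or unnamed intergenic loci. On the lower side Asxl3, Adamts20, Hist1h4d, Plxnb1 and Atp6v0c had log2 fold changes of −5.13, −2.77, −2.19, −1.62 and −1.44 in the authors' deposited table and of −1.52, 0.00, −0.36, −0.23 and −0.47 without control replicate 2. Lin52 and Mrpl52 turned from −2.68 to 0.06 without control replicate 2 and from −1.30 to 0.11 without control replicate 3.

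In all, 77 of 17545 tested loci had an FDR of at most 0.05 in the authors' deposited table, 54 higher and 23 lower with ketamine. Libraries did not overlap at 45 of these loci, or 58.4% against 11.5% of all tested loci and 10% by chance. Here too, picking calls on the same libraries by itself raises this share. Fisher's exact test across genes gave adjusted p-values of 0.00145 (immediate early genes), 0.0342 (choroid plexus) and 0.0369 (meningeal). Limma's fry, with libraries as replicates, gave adjusted p-values of 0.481 (immediate early), 0.708 (choroid plexus) and 0.704 (meningeal) for a shift in 1 direction, so none of the 3 lists passed, nor did any for change in either direction. Limma called 2 loci at an adjusted p of at most 0.05, short loci of Mtap7d1 and of Dbndd2, Gm20458 and Sys1 that were listed at 0 in control, and 1076 loci at an unadjusted p under 0.05. Without control replicate 2 it called 13 loci, all higher.

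The design also asks whether the 3 treatments changed the same genes. Called genes were joined by name, since each table had its own loci, and loci of the same name need not overlap, as for Ccdc135 in the siGSK3b and L803mts tables, singled out after its values were seen. In all 3 comparisons 5 genes were called in the same direction: Kcne2 and Tmem72 higher, and Adamts20, Hist1h4d and Rplp1 lower. Without control replicate 2 none of the 5 kept at least 0.5 of its log2 fold change in each table, and without control replicate 3 the 3 lower genes did. SiGSK3b and L803mts shared 24 genes, 19 higher and 5 lower, where independent lists would share 0.293 and 0.0267. That value leaves out the shared controls and so is not what unchanged groups would give. The higher genes included Ttr, Tmem72, Kcne2, F5, Folr1, Kl, Otx2, Igf2, Igfbp2, Sgk1 and Ppp1r1b, and the lower genes Kcnj2, named after the values were seen. For Sgk1, Ppp1r1b and Kcnj2 the treated libraries did not overlap with the control libraries in either table. In the ketamine table Sgk1 was at 25.5 ± 6.67 against 20.8 ± 1.96 FPKM and Kcnj2 at 10.7 ± 0.431 against 12.5 ± 2.0, neither past the test, and whether these effects differed from those of the other treatments was not tested. SiGSK3b and ketamine shared 9 genes, 2 higher and 7 lower, and L803mts and ketamine 7, 2 higher and 5 lower, and without control replicate 2 these counts were 2 and 1. Zic1, a transcription factor gene of the thalamus, was called in opposite directions, with log2 fold changes of −1.24 for siGSK3b and 1.24 for L803mts in the authors' deposited tables. These values come from loci that do not overlap (chromosome 9, 91252769 to 91255844 and 91260141 to 91260639), so they do not show the same region going opposite ways. Without control replicate 1 that for siGSK3b was 0.23, and without L803mts replicate 1 that for L803mts was 0.39.

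The 3 comparisons used the same control libraries, so part of any overlap may come from them, and 3 control libraries cannot be split into parts of at least 2. Across genes, log2(FPKM + 1) fold changes correlated at 0.35 (siGSK3b and L803mts), 0.38 (siGSK3b and ketamine) and 0.30 (L803mts and ketamine). Unchanged groups simulated with a shared control gave a mean correlation of 0.50 for each pair over 200 simulations. The simulation drew all groups with the same spread per gene. This alone sets the correlation near 0.50, so the lower observed values decide nothing. The covariances were 0.0241, 0.0235 and 0.0189, against simulated means of 0.0264, 0.0251 and 0.0253. The spread of the control libraries alone gives a covariance of 0.0209, 0.0213 and 0.0206, which the observed value exceeded by 0.00316 and 0.00218 for both siGSK3b pairs and not for L803mts and ketamine. Genes ranked by their difference over the spread between libraries, in lists as long as those of the called genes, shared 7, 3 and 2 higher genes for the same pairs, against simulated means of 9.32, 6.04 and 9.36. They shared 0, 2 and 1 lower genes, against 2.05, 2.88 and 1.70. By this ranking the overlap was not above that of the simulated groups. The simulation drew genes independently, while choroid plexus genes varied together between the control libraries. It therefore cannot tell how much overlap the shared controls gave. Genes are not independent replicates.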

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

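Calls with libraries that do not overlap, the 0.1 pseudocount and fry were chosen only after the data were seen. At an FDR of at most 0.01 all counts of called and shared genes were 0, because the smallest FDR the p-value floor allows is higher. Requiring libraries that do not overlap left 32 (12 higher, 20 lower), 47 (42, 5) and 45 (39, 6) calls for siGSK3b, L803mts and ketamine, so that for siGSK3b 37.5% were higher against 55.4% of all calls. Limma's counts of 1, 0 and 2 ran from 0 to 36, 0 to 36 and 1 to 13 when a library was left out, and median-centred libraries gave 2 for siGSK3b. Of the authors' calls 78 to 82, 82 to 110 and 66 to 77 kept at least 0.5 of their fold change without a single library, and 69, 64 and 56 did so without each in turn. Genes called in all 3 comparisons fell from 5 to between 0 and 5, and those shared by siGSK3b and L803mts, siGSK3b and ketamine, and L803mts and ketamine ranged over 20 to 24, 2 to 9 and 1 to 7. With control values within 10% between tables these counts were 1, 7, 4 and 2. This setting left 4329, 4566, 4542 and 4583 joined genes, against 12837, 13197, 13194 and 13380, so fewer shared genes could be found. The deposited fold changes correlated at 0.126, 0.327 and 0.115 for the same pairs. These became 0.30 and 0.280 (first and last pair) at a mean of at least 1 FPKM, 0.348 and 0.301 on log2(FPKM + 1), and 0.457, 0.476 and 0.404 with control values within 10%. The cause was not tested.

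Of 97 named calls with a finite log2 fold change 37 kept under 0.5 of it without a single library, and 5 changed sign. When each library was left out, the fold changes of these 5 ran from −1.74 to 0.23 (Zic1, siGSK3b), −0.28 to 3.32 (Nudt13, L803mts), −2.05 to 0.28 (Hist1h4d, L803mts), −3.20 to 0.063 (Lin52, ketamine) and −1.71 to 0.11 (Mrpl52, ketamine). No named call was lost on readjustment and none reversed on log2(FPKM + 1). Of 941 alternative values 847 stayed the same (a count within 1.5 times, a correlation within 0.1, or a gene keeping its sign, and without a library 0.5 of its fold change), 89 moved and 5 changed sign. The labels do not say that the replicate numbers pair the libraries. In their deviations from the group means, same-numbered libraries correlated from −0.164 to 0.011 (siGSK3b), 0.013 to 0.188 (L803mts) and 0.042 to 0.141 (ketamine). Not each library correlated best with its own number. With 3 libraries per group this cannot exclude a pairing, and none was assumed in the main tests. With the replicate number as a block limma called 2, 0 and 1 loci. Depth is unknown, and so is what it limits.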

Other observations

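Both tests on the choroid plexus pattern, the median over all tested pseudogene and unnamed loci, the matched random sets, fry and the list medians over single control libraries were chosen only after the result was seen; the other tests here were written before.

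Lists not described above also stood apart. In the libraries labelled siGSK3b 17 of 18 myelin and mature oligodendrocyte genes were below control, with a median log2 fold change of −0.23, lower than any of 10000 random lists. Mobp fell, and Mbp, the myelin basic protein gene, was at 392 ± 45.1 FPKM against 480 ± 8.63, Mag at 17.1 ± 2.31 against 22.1 ± 0.863 and Opalin at 1.14 ± 0.247 against 2.07 ± 0.199, none of these 3 past the test and all 3 singled out after their values were seen. The list mean in log2(FPKM + 1) was 4.75, 4.81 and 4.89 against 5.15, 5.07 and 4.92 in control (fry, adjusted p = 0.441). With ketamine 16 of 20 members were below control, 0 were called, and 6 fell adjusted over the list alone; Cuffdiff and limma each had 6 lower at an unadjusted p under 0.05. Ependymal and motile cilia genes were above control for 12 of 14, 12 of 14 and 13 of 15 members with siGSK3b, L803mts and ketamine, with 0 called in each by Cuffdiff. At an unadjusted p under 0.05 the authors' test had 3, 4 and 3 of them higher, and limma 0, 1 and 1. Their mean log2(FPKM + 1) in the control libraries of the siGSK3b table was 2.83, 2.19 and 2.08, so control replicate 1 was highest here too.

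With libraries as replicates, fry found 3 lists changed in either direction, glucocorticoid response and meningeal markers with L803mts and endothelial and mural cell markers with ketamine (adjusted p = 0.0104 each), and 0 to 11 when a library was left out. In the latter list Cnn1, singled out after its values were seen, the calponin gene of smooth muscle, was at 107 ± 7.84 FPKM with ketamine against 63.1 ± 0.968 in control. Limma gave Cnn1 an unadjusted p of 1.8e-05, and the authors' deposited table an FDR of 0.860.

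Choroid plexus genes called higher with siGSK3b and L803mts were weighed against the amount of this tissue in each library. For a treatment effect over a level common to the 3 controls, at most 4.55% of the list had every treated library above every control library (0 of 21 and 1 of 22). Control replicate 1 had already been seen at the treated level, so this test could hardly pass and decides nothing about treatment. Every treated library lay above control replicates 2 and 3 at 21 of 21 members with siGSK3b and 22 of 22 with L803mts. The higher of the 2 medians of the treated mean over control replicate 1 was −0.029, which may mean that libraries differ in how much choroid plexus was dissected with the hippocampus, whatever their treatment. Control replicate 1 lay above the lowest treated library at 32 of 46 loci called higher with siGSK3b and 31 of 98 with L803mts. A treatment effect in addition to different amounts of tissue stays open.

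For L803mts 29 loci called higher lost over 0.5 of their fold change without replicate 3, among them Syn1, Shank3 and Vamp2. After correction for GC content and transcript length, 90.0% of their median deviation was left (1.06 before and 0.96 after, standard error 0.04, 28 of 29 loci matched). GC content and length explained 14.1% of the variance of this deviation over the other loci. The 29 loci were picked through replicate 3, so most of their deviation was likely to remain, and the test cannot exclude such a bias. Their median GC content was 55.1%, against 48.6% over all matched loci. For striatal, thalamic or neocortical tissue in replicate 3, the highest of the 3 list medians of its deviation from replicates 1 and 2 was −0.017. The striatal median was −1.04. Replicate 1 was itself highest for striatal and thalamic markers, so this deviation cannot exclude such tissue. Replicate 3 had a striatal mean in log2(FPKM + 1) of 2.82, against 3.06, 2.72 and 2.65 in control. Its thalamic mean was 3.14, against 3.02, 3.015 and 2.88, and its neocortical mean 2.57, against 2.19, 2.56 and 2.46. Immediate early genes (0.51), dentate gyrus markers (0.51) and synaptic genes (0.35) were higher in replicate 3 than in replicates 1 and 2. The dentate gyrus mean of 4.03 was near that of control (3.78, 3.95 and 3.81), with 3.44 and 3.63 in replicates 1 and 2. A response to L803mts in this library alone was not tested and stays open.

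With ketamine 21 pseudogene and unnamed loci rose, by log2 fold changes of 0.53 to 1.49 in the authors' deposited table, and at 20 of them the libraries did not overlap. The 1623 tested loci of these types that were not called had a median log2(FPKM + 1) fold change of 0.039. This test leaves out the called loci and so decides nothing. A rise common to all such loci is argued against, since all 1647, called or not, had a median of 0.041 and quartiles of −0.10 and 0.17. These values are on log2(FPKM + 1), which shrinks the changes of low loci but keeps their sign. The deviations of the 21 loci from their group means had a median pairwise correlation of 0.702, just over the bound of 0.7 written before. Over 1000 random sets of uncalled loci picked for nearest length and level, the highest such value was 0.512. The uncalled loci were near in level (median FPKM 29.5 against 33.4) but longer (median 1526 against 860 bases). A candidate explanation is a repeated sequence whose reads were placed at many of the 21 loci. Their median length was 860 bases, against 4286 for all loci of these types that were not called. A ketamine effect on the source of such reads stays open.

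The 10 splits of 6 libraries are too few for a share under 0.05. Limma's real counts were 1, 0 and 2 for siGSK3b, L803mts and ketamine, the highest of the other splits 3, 1 and 60, and 5, 10 and 3 splits gave as many. The split with 60 loci set control replicate 1 and ketamine replicates 1 and 2 against the rest and points to a structure of the samples; 59 of its loci were lower in the rest, 18 were choroid plexus genes, and Ppp1r1b was among the loci (limma, adjusted p = 0.023).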
